A study of Arabidopsis thaliana with 4 samples.

How the data were processed

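Shoot apices of 6-week-old Arabidopsis thaliana plants grown at 22 °C with 16 h of light and 8 h of dark were sampled after removal of older flowers, per the labels' protocols. Poly(A) RNA was made into strand-specific libraries and sequenced as read pairs of 100 bases on an Illumina HiSeq instrument, per the labels' protocols. The labels put 2 libraries in clv3 and 2 in mp clv3. CASAVA 1.7, BWA and the build TAIR10 are named, per the submitters' processing notes. How reads were counted, whether strand was used and which test gave the FDR are not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty.

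The authors deposited a table with 1 column of read counts per gene and genotype, per the file headers. Whether a column is the sum of both libraries or another combination is not stated. Genes without reads carry 0.5 in the deposited counts, which was read as 0. Values from 1 to 9 were even in 83.3% of cases in clv3 and 82.5% in mp clv3, against 49.6% and 49.3% for values of at least 1000, so both mates of a pair seem to be counted separately. The deposited RPKM are those counts scaled to gene model length and to the column total, per the file headers and as recomputed from the values. The log2 ratio of the authors is that of mp clv3 over clv3, and recomputing it from the deposited RPKM gave a largest difference of 1.0e-13. An FDR (an adjusted p-value) per gene is also the authors' own, per the file headers, and is listed as 0 for 1834 genes.

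Of 27323 genes in the table, 1 (AT1G01010) had other content in its cells and was left out, which leaves 27322. Gene names came from the RefSeq annotation of TAIR10.1, in which 26643 identifiers were matched, and no coordinates were taken from it since the build differs. The planned test across replicate libraries was not possible because each genotype has 1 column. Calls are therefore those of the authors' deposited table at an FDR under 0.05, and no p-value across genes was computed except an exact binomial test on reads or read pairs with Benjamini-Hochberg adjustment, which compares these columns and not the genotypes. Since the table gives no unadjusted p, no adjustment over a list alone could be made.

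Folds were computed from the reads and the ratio of the column totals (1.03). Their exact Clopper-Pearson intervals at 95% were computed on read pairs, that is reads divided by 2. The floor was 3 read pairs, or 6 reads, per column. A gene at 0 in a column was set to that floor and its fold given as a lower bound, and no fold is given where both columns are at or under it. This bound leaves out the counting error of the other column. For the column at 0, its floor of 3 read pairs is also smaller than the upper limit of the 2-sided 95% interval. The bound therefore lies above the lower end of the gene's exact interval, as for MS2 with 3397 against 2762. For genes with many reads in the other column, such as MS2, the floor makes most of this gap. PCR copies are not independent molecules, so intervals and floors cover counting error only.

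Gene lists (14 lists, 327 genes, 325 of them measured) were fixed before the data were examined. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean RPKM in 20 bins, as a description of these columns. The rule for naming genes, also fixed then, took MP and CLV3, the 10 largest changes each way among genes with an FDR under 0.05 and at least 100 reads in the higher genotype, and the 4 largest changes in each list. Changes were ranked by the log2 ratio with 0 reads as 0.5. The part of the rule that asks for both libraries of a genotype above both of the other could not be applied. Every other gene was chosen after its values were seen, which in the report holds for WUS, STM, CLV1, CUC1, CUC2, CUC3, ARR5, CKX3, LOG1, LOG4, LOG7, GH3.6, IAA18, PIN7, YUC4, TAA1, AP1, LFY, UFO, PAN, SPT, FUL, SEP4, PI, SEP3, LAP6, PHB, AIL7, SVP, COR15A, KIN2, RD29A, LOX2, VSP1, VSP2, TAR2, YUC2, YUC6, CKX1, CKX2, IPT1, IPT5 and AT2G17850, and for DRN within the stem cell list. It also holds for every gene that the closing section names and the report does not.

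The exact binomial test and the intervals were tested on simulated counts for the 27322 genes of this comparison. The test recovered 99% of 100 genes changed 2-fold and 99% of 100 changed 4-fold, with 5 calls among 27122 unchanged genes. The intervals covered the true ratio in 95.9% of cases. The simulated counts held counting error alone, without spread between plants. The changed genes and those behind the coverage were picked from genes with more reads. These figures therefore do not give the error of the authors' calls. Alternatives were quantile normalization, a minimum of 100 reads, pseudocounts of 1 and 0.1, a minimum fold of 2 and, added after seeing the data, a minimum of 1 RPKM, median scaling, exact tests on read pairs and a ranking with every count under the floor set to it. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.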

Results

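The transcriptome of shoot apices from 6-week-old Arabidopsis plants was measured by RNA-seq in clv3 and in mp clv3, which carries mutations in both genes. CLV3 encodes the secreted peptide that limits stem cell number at the shoot apex, and MP (MONOPTEROS, ARF5) encodes an auxin response factor that acts in flower initiation. The labels describe 4 libraries, 2 per genotype, but the values come as 1 column of reads and 1 column of RPKM (reads scaled to gene model length and to the column total) for each genotype, so the spread between libraries is unknown and the difference has no replicate check. The clv3 column holds 100328819 reads over 24172 genes, and the mp clv3 column holds 103347441 reads over 22616 genes. The growth description in the labels names Col-0 where the genotype labels say clv3, so clv3 here means the plants labelled that way. The series title states no question beyond the comparison of these genotypes.

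Anther genes and most floral identity genes were lower in mp clv3 than in clv3, many of them by over 100-fold, while most cytokinin genes and most stress genes were higher. Stem cell and boundary genes went both ways, with 21 of 32 lower and 9 higher in the authors' deposited table. At least 2-fold, 12 were lower and 6 higher, and the meristem genes WUS and STM were among the higher ones. AP3, a MADS-box gene needed for petals and stamens, had 7610 reads (73.1 RPKM) in clv3 and 2 reads in mp clv3. MS2, which acts in building the pollen wall, had 19785 reads in clv3 and 0 in mp clv3, at least 3397-fold lower. ARR7, a type-A response regulator that dampens cytokinin signalling, had 22.4 RPKM in clv3 and 135 RPKM in mp clv3, 6.01-fold higher with a 95% counting interval from 5.60 to 6.45. PR2, a defence glucanase listed as BGL2 in the reference, had 0.471 RPKM in clv3 and 181 RPKM in mp clv3.

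The targeted genes were looked at to check the labels. MP had 25336 reads (74.8 RPKM) in clv3 and 5063 reads (14.5 RPKM) in mp clv3, 5.15-fold lower with an interval from 4.94 to 5.38. Reads on MP therefore remained in mp clv3, and where the mutation lies in the gene was not used here. CLV3 had 110 reads (1.4 RPKM) in clv3 and 1278 reads (15.8 RPKM) in mp clv3, 11.3-fold higher with an interval from 8.56 to 15.1. Both genotypes are labelled as clv3 mutants, so this gene does not tell the labels apart.

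In the authors' deposited table, 19857 of 27322 genes (72.7%) had a false discovery rate (FDR) under 0.05, with 7206 higher and 12651 lower in mp clv3. Of these, 2549 were at least 2-fold higher and 5044 at least 2-fold lower. The sources used here do not name the test behind that FDR, and an exact binomial test on the reads alone, which holds no spread between plants, fell on the same side of 0.05 as the authors' deposited table for 99.0% of genes. The median log2 ratio of the 18832 genes with a mean of at least 100 reads was -0.12, and with that median set to 0 an exact binomial test on read pairs gave 8136 higher and 9248 lower genes. Every gene named in the text as higher or lower had an FDR of at most 0.0236 in the authors' deposited table.

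Ranked by log2 ratio with 0 reads standing as 0.5, as in the authors' deposited table, the 10 genes furthest up had at most 3 reads in clv3. With every count under the floor of 6 reads set to it, 3 of these 10 stayed in the ranking and AT2G17850 (1198-fold) came first. SRO4, of the family of RCD1-related proteins, had 2 reads in clv3 and 6095 in mp clv3 (50.1 RPKM), a ratio of 2958 with an interval from 531 to 116889. XTH18, a cell wall xyloglucan-modifying enzyme, had 2 and 5876 reads, and AT3G29970, a B12D protein, had 3 and 6420 reads. Against 0 reads in clv3, the WD40-repeat gene AT4G34380 was at least 224-fold higher, the zinc finger gene ZAT7 at least 213-fold, and the pectin methylesterase inhibitor family gene AT2G47550 at least 209.5-fold. AOX1D, an alternative oxidase of mitochondria, was at least 142-fold higher. The berberine-enzyme family genes AT1G30730 and AT4G20860 were at least 173-fold and 140.4-fold higher, and the oxygenase gene AT2G38240 at least 139-fold.

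By the same ranking, the 10 genes furthest down had 0 reads in mp clv3, led by MS2. With every count under the floor set to it, MS2 alone stayed among the 10, and MEE48, an anther glucanase-type gene, came first at 4475-fold lower with an interval from 1748 to 16428. The lipid-transfer type gene A7 was at least 1243-fold lower (94.0 RPKM in clv3), and ATA1, annotated as TAPETUM 1, at least 749-fold. The others were AT1G68875 (at least 1192-fold), LCR66 (1098-fold), the fasciclin-like gene AT5G16920 (999-fold), the GDSL-lipase gene AT1G20130 (789-fold), AT1G02813 (786-fold), the lipid-transfer type gene AT1G66850 (687-fold) and RHS14 (676-fold).

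All 18 measured tapetum and pollen genes were lower in mp clv3 in the authors' deposited table, each by at least 2-fold, and their median log2 ratio was -10.00 (-9.86 with genes at 0 set to the floor). MEE48 had 34757 reads in clv3 and 8 in mp clv3. AT5G07230, a tapetum gene, had 8430 and 2 reads, and CYP704B1, which makes pollen wall precursors, had 9077 and 3. Reads remained for others, such as LAP6, of the pollen wall pathway, with 21948 and 1811. Of the 23 floral identity regulators, 17 were lower and 6 higher in the authors' deposited table, with a median log2 ratio of -6.95 (-5.53 at the floor). The ratio for AP3 was 3919.6 with an interval from 703 to 154855. SEP2 and SEP1, MADS-box partners in floral organ identity, had 7415 and 5930 reads in clv3 and 2 each in mp clv3, and BOP2, a boundary and floral patterning gene, had 2188 and 2. AP1 had 103.5 RPKM in clv3 and 0.158 in mp clv3, while LFY, which specifies floral fate, had 24.5 and 27.4 RPKM. The others higher in mp clv3 were SPT (3.49-fold), PAN (3.03-fold), UFO (2.52-fold), FUL (1.81-fold, AGL8 in the reference) and SEP4 (1.31-fold), and FUL and SPT stood there at 152 and 128 RPKM. Both lists had medians below those of all 10000 random lists matched on mean RPKM.

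The stem cell and boundary list was divided, with 9 of 32 genes higher and 21 lower in the authors' deposited table. WUS, the homeobox gene that maintains stem cells, was 3.83-fold higher (5.69 to 21.8 RPKM, interval 3.4 to 4.31), and STM, which keeps meristem cells undifferentiated, was 2.2-fold higher. DRN, an AP2-type gene listed as ESR1 in the reference, was 12.2-fold higher and CLV1, a receptor for CLV3, 1.99-fold. Among the lower members, HEC2 and HEC3, bHLH genes of the gynoecium and apex, had 414 and 134 reads in clv3 and 2 each in mp clv3. LAS, needed for axillary meristems, had 293 and 4 reads. PUCHI had 16 and 0 reads, at least 2.75-fold lower by the floor, with an exact interval that starts at 1.76. The boundary genes parted, since CUC1 was 2.51-fold higher while CUC2 was 3.32-fold and CUC3 8.61-fold lower. The list's median log2 ratio was -0.47, at percentile 0.51 of the random lists.

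**Figure D1:**
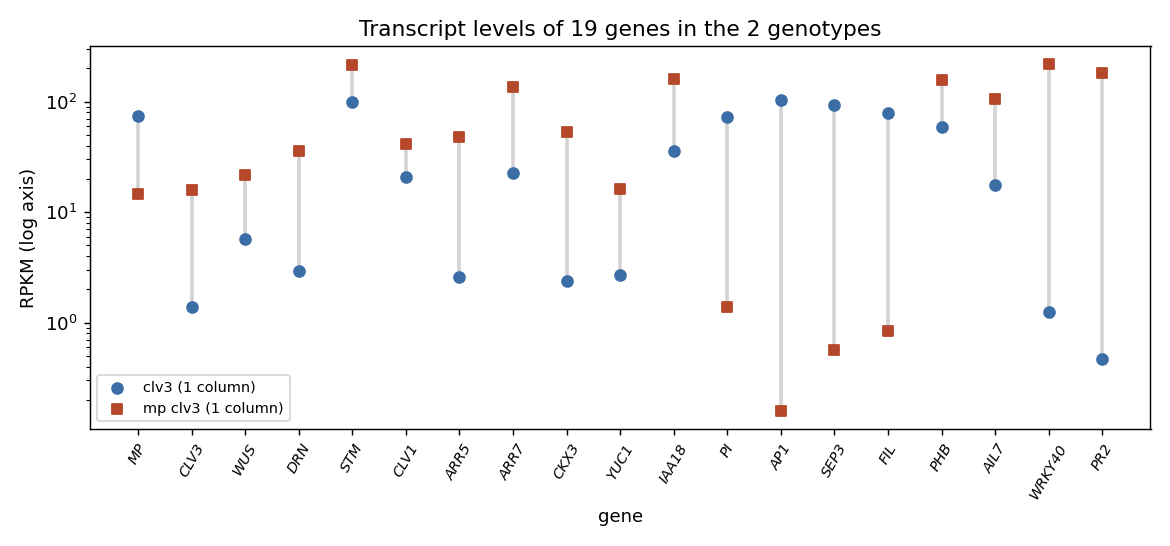
RPKM of 19 genes (y axis, log scale) in the 1 column of clv3 (circles) and the 1 column of mp clv3 (squares), with no error bars since no values per library were used. WUS, DRN, ARR5 and CKX3 lie higher in mp clv3, while MP and the floral genes PI, AP1 and SEP3 lie lower, AP1 at 103.5 against 0.158 RPKM.

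Cytokinin genes were mostly higher in mp clv3, with 21 of 30 higher and 8 lower in the authors' deposited table and a median log2 ratio of 0.76, at percentile 100 of the random lists. All 10 type-A response regulators were higher, 7 of them by at least 2-fold. ARR5 was 18.4-fold higher (2.60 to 47.8 RPKM). ARR3 and ARR17 had 0 reads in clv3 and 32 each in mp clv3, at least 5.18-fold higher by the floor, with exact intervals that start at 3.74. CKX3, a cytokinin oxidase that degrades the hormone, was 22.6-fold higher (2.37 to 53.6 RPKM), and 5 of 7 CKX genes were higher and 2 lower in the authors' deposited table, CKX1 by 7.21-fold and CKX2 with 12 and 2 reads. Of the biosynthesis genes, IPT7 had 0 and 26 reads, at least 4.21-fold higher by the floor, with an exact interval that starts at 2.96. In contrast, IPT1 was 2.04-fold lower and IPT5 had 16 and 2 reads. The LOG genes, which activate cytokinin, parted, with LOG3 23.9-fold and LOG1 16.2-fold lower while LOG4 was 4.1-fold and LOG7 4.84-fold higher.

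Auxin genes went both ways. Of 18 reported MP targets, 8 were higher and 9 lower in the authors' deposited table, with a median log2 ratio of -0.01 at percentile 78.2, or -0.19 at percentile 26.7 without 1 gene at the floor. No expected direction was set for each target, so this median does not tell whether the targets as a group responded. FIL, a YABBY gene of the abaxial side of organs listed as AFO in the reference, was 93.9-fold lower. IAA20 was 7.73-fold and AT5G66940, a DOF-type gene of early vascular cells, 5.94-fold lower, whereas DRN and ARR7 were higher. In the authors' deposited table, 12 of 32 Aux/IAA and GH3 genes, many but not all of which respond to auxin, were higher and 15 lower. The list's median of -0.10, at percentile 68.0, turned to 0.02 when the median of genes with a mean of at least 100 reads was set to 0. GH3.2 (BRU6 in the reference) and GH3.3, which conjugate auxin to amino acids, were 15.1-fold and 14.5-fold lower and the repressor IAA14 was 13.5-fold lower. GH3.6 was 6.84-fold and IAA18 4.47-fold higher. GH3.4 had 6 reads in clv3 and 0 in mp clv3, which is at the floor, so no fold is given.

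Among 14 auxin response factors, 4 were higher and 8 lower in the authors' deposited table, with a median log2 ratio of -0.30 at percentile 7.29. ARF11 was 2.93-fold, ARF17 2.64-fold and ARF18 1.91-fold lower, and ARF19 was 2.09-fold higher. Auxin transport and biosynthesis genes had 8 members higher and 19 lower of 30 in the authors' deposited table, with a median of -0.60 at percentile 0.33. The auxin exporter PIN7 was 5.90-fold lower, and WAG1, a kinase that acts on PIN proteins, was 6.56-fold lower. The synthesis genes YUC1 (5.93-fold), YUC4 (4.65-fold), TAA1 (3.35-fold) and YUC8 (6.01-fold, 16 and 99 reads) were higher, while TAR2 (3.76-fold), YUC2 (2.79-fold) and YUC6 (1.85-fold) were lower and YUC9 had 6 and 0 reads, at the floor.

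Of 25 genes of lateral organ outgrowth and polarity, 15 were lower and 9 higher in the authors' deposited table, with a median log2 ratio of -1.30 (-1.17 at the floor), below all random lists. JAG, which promotes organ growth, was at least 134-fold lower and WOX1, of the blade margin, at least 86.2-fold lower. YAB2 had 1967 and 2 reads, and AS2, a leaf polarity gene, had 929 and 4. All 5 YABBY genes were lower, with a median of -6.55, while PHB, an adaxial class III HD-ZIP gene, was 2.70-fold higher and AIL7, of the AINTEGUMENTA-like group, 6.00-fold higher. Among 15 inflorescence and flowering-time genes, 6 were higher and 8 lower in the authors' deposited table, with a median of -0.72 at percentile 0.17. FT, the mobile flowering signal, had 352 and 2 reads, SPL5 was 40.1-fold lower, LMI1 (HB51 in the reference) 17.9-fold lower and the floral repressor FLC 14.3-fold lower. SVP, a repressor of flowering, was 3.49-fold higher.

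Cell division genes differed by small amounts in a common direction, with 27 of 30 lower and 2 higher in the authors' deposited table, 6 of the lower ones by at least 2-fold, and a median log2 ratio of -0.63. CYCD1;1 was 2.70-fold, CYCB2;1 2.58-fold, CYCB1;2 (CYC1BAT in the reference) 2.31-fold and CYCA1;1 2.29-fold lower. Photosynthetic genes were lower in 25 of 27 cases in the authors' deposited table, with a median of -0.77. The Rubisco small subunit genes RBCS2B (27.0-fold), RBCS3B (10.4-fold) and RBCS1B (10.4-fold) were lower. These copies are near-identical and how reads that match several copies were counted is not given, so their separate values are uncertain. The light-harvesting gene LHCB1.2 (CAB3 in the reference), 3.42-fold lower, also has close copies. The medians of both lists lay below all random lists. Vascular genes were lower in 17 and higher in 3 of 21 cases in the authors' deposited table, with a median of -1.07 at percentile 0.02. NST1, a regulator of fibre walls, had 106 and 2 reads, and LAC4 (IRX12 in the reference), a lignin laccase, was 4.87-fold and the xylem peptidase XCP2 3.1-fold lower.

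Stress, wounding and defence genes were higher in 18 and lower in 6 of 26 cases in the authors' deposited table, with a median log2 ratio of 1.18 at percentile 100. PR2 was 384-fold higher with an interval from 268 to 572. WRKY40, a rapidly induced defence regulator, was 175-fold higher (1.26 to 221 RPKM), and ZAT12 (RHL41 in the reference), a stress zinc finger gene, 104-fold. The defensin PDF1.2 had 0 reads in clv3 and 472 in mp clv3, at least 76.4-fold higher. The 6 lower members were the cold and drought genes COR15A (21.5-fold), KIN2 (2.73-fold) and RD29A (1.29-fold, LTI78 in the reference) and the jasmonate and wounding genes LOX2 (2.71-fold), VSP1 (1.43-fold) and VSP2 (1.37-fold).

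**Figure D2:**
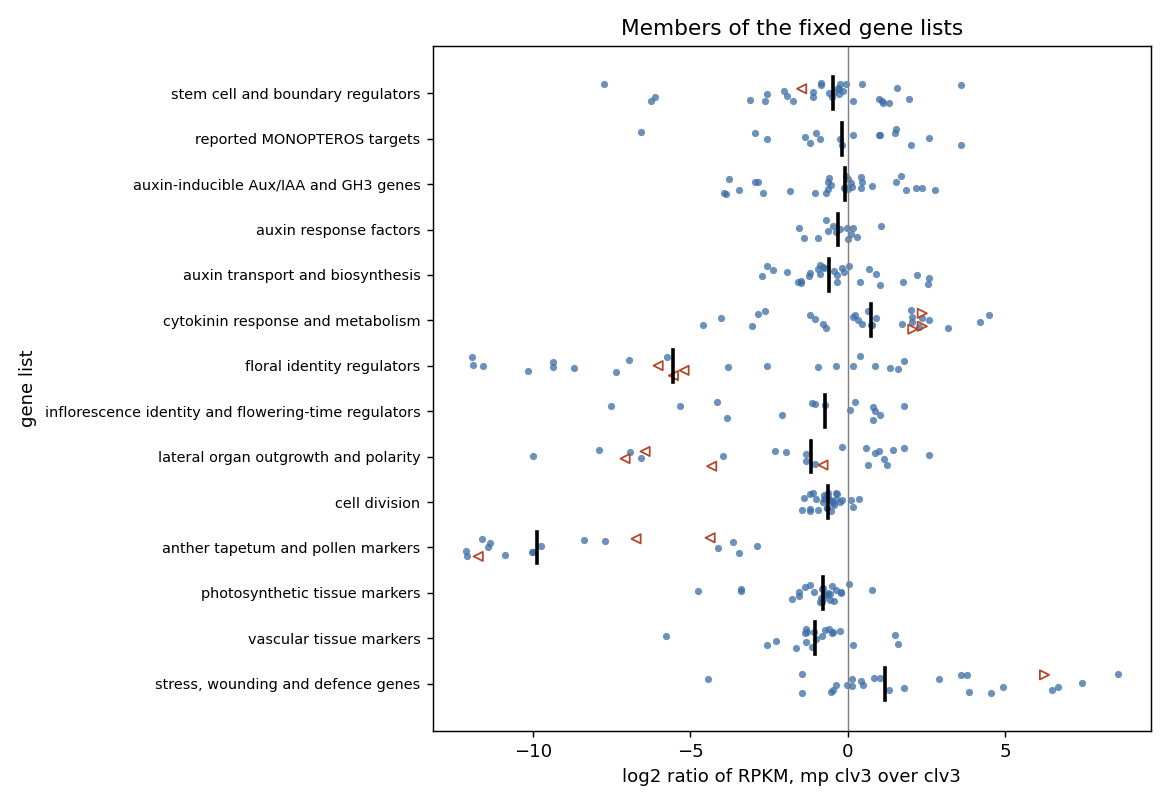
Log2 ratio of RPKM, mp clv3 over clv3 (x axis), of each measured member of the 14 gene lists (y axis), with points for genes with reads in both columns, open triangles for genes at 0 in a column set to the floor, and bars for list medians. Genes at or under the floor in both columns are left out, and the anther list has its median at -9.86 and the stress list at 1.18.

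With no values per library, none of these differences could be set against the spread between plants, and the intervals cover read counting alone. All 18 tapetum and pollen genes and 17 of 23 floral identity genes were lower in mp clv3 in the authors' deposited table, so the tissue makeup of the apices can differ beside every other list.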

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

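No paired analysis was possible because each genotype has a single column without replicate numbers. For the same reason leaving out a library, tests across replicates and list tests with a correlation between genes were not run. Median scaling, the minimum of 1 RPKM, the ranking at the floor and the tests on read pairs were chosen after the data were seen. Asking for at least 2-fold took the differing genes from 19857 to 7593, the higher ones from 7206 to 2549 and the lower ones from 12651 to 5044. Genes at least 2-fold higher numbered 1692 with a pseudocount of 1. Those at least 2-fold lower numbered 2584 with a mean of at least 100 reads, 2237 with a pseudocount of 1 and 2924 with at least 1 RPKM in either column, since these settings remove or shrink low genes. Aux/IAA and GH3 members at least 2-fold lower were 10, and 5 with at least 100 reads, 5 with a pseudocount of 1 and 6 with at least 1 RPKM. Vascular members at least 2-fold lower were 11, and 6 with quantile normalization and 5 with a pseudocount of 1, for which the cause was not tested. The other 107 of 112 list counts stayed within 1.5 times. Exact tests on read pairs called 17593 genes, 6437 higher and 11156 lower. Of 598 values of the 77 genes named by rule under these settings, 594 kept their direction and their side of 0.05. None turned direction, and 4 lost the call, all of GH3.4 and YUC9 with 6 and 0 reads. Only the exact tests on read pairs could change a call, since the other settings kept the authors' FDR and all these genes were under 0.05. Direction could turn only under quantile normalization and median scaling. Most of the 594 were therefore fixed in advance and do not measure how firm the calls are. Genes with up to 6 reads in both columns are given no fold, though GH3.4 and YUC9 had an FDR of 0.0236 in the authors' deposited table and are counted as lower in their lists.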

Other observations

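The tests and gene groups in this part were chosen after results had been seen, except the test on the time of day. Genes that plants induce when oxygen is low had much higher levels in mp clv3. All 44 members of a low-oxygen list were higher in the authors' deposited table, 42 of them by at least 2-fold, with a median log2 ratio of 3.94. ADH1, the alcohol dehydrogenase of ethanol fermentation, had 12.7 RPKM in clv3 and 1019 RPKM in mp clv3, 80.4-fold higher with an interval from 75.4 to 85.9. HB1, a haemoglobin that binds oxygen and nitric oxide, was 137-fold higher, SUS4, a sucrose synthase, 105-fold, PDC2, a pyruvate decarboxylase, 4.16-fold and LBD41 12.6-fold. ERF71, of the group VII ethylene response factors, was 419.9-fold higher with an interval from 221 to 919.

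Further gene families were counted as well, and some of their members, such as WRKY33 and JAZ1, also stand in the stress list. Of 67 WRKY transcription factors, 40 were higher and 12 lower in the authors' deposited table, with a median log2 ratio of 0.96, and WRKY33, which acts against fungi, was 30.4-fold higher. JAZ repressors of jasmonate signalling were higher in 8 of 10 cases and lower in 1 in the authors' deposited table, with JAZ1 14.4-fold higher. Cysteine-rich receptor-like kinases were higher in 27 and lower in 7 of 38 cases in the authors' deposited table. Xyloglucan endotransglucosylase genes went both ways (10 higher and 12 lower of 30 in the authors' deposited table), as did alpha-expansins (4 higher and 10 lower of 23). Of 81 chloroplast genome genes, 78 were lower and 0 higher in the authors' deposited table, with a median of -0.66, and 2 of them turned higher under quantile normalization. They held 0.80% of the reads in clv3 and 0.50% in mp clv3. The libraries were made from poly(A) RNA, and how well these sample chloroplast transcripts was not tested.

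The low levels of anther, pollen and floral genes in mp clv3 were set against technical explanations. A common scaling factor would shift all genes alike, but the anther list's median lay at -9.90 from that of all genes, which argues against it. Fewer reads cannot account for it either, since the total of mp clv3 was 1.03 times that of clv3. Less floral tissue in the mp clv3 samples, from the genotype or from the removal of flowers at harvest, and lower levels within such tissue cannot be told apart, since the floral identity list, with a median of -6.95, is part of the pattern itself. The 6 floral identity genes that were higher in the authors' deposited table and the 1811 reads of LAP6 in mp clv3 are not accounted for.

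The stress and low-oxygen genes were weighed in the same way. Concentration of the remaining tissue would raise vascular and stress genes alike if both lists stood for that tissue. The stress median lay 2.25 above the vascular one (95% bootstrap interval over genes 1.09 to 4.92), so the lists did not rise alike. The vascular list was itself lower, with a median of -1.07, so it cannot exclude that another remaining tissue became more concentrated. A brief stress at harvest cannot be told apart from a lasting state, since the labels give no handling times, neither for the low-oxygen genes (median 3.94) nor for the defence genes PR1, PR2, PR5 and PDF1.2 (median 6.38, with PDF1.2 set to the floor in clv3), which were picked after their values were seen and so decide nothing. For harvest at another time of day, the sign set beforehand was morning and evening clock genes moving in opposite directions with medians far apart. That sign was not met, since 6 morning genes had a median of 2.13 and 7 evening genes 0.62, both higher in mp clv3. The difference of 1.51 (0.74 to 3.49) was still too large to set this explanation aside by the limit chosen, so it stays open. A low-oxygen type of response in the mp clv3 tissue is a hypothesis that the 38 low-oxygen genes whose values had not been seen are consistent with, at a median of 3.74 against -0.26 to 0.07 in random lists.

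The growth description names Col-0 and the genotype labels clv3 for the same libraries. CLV3 had 1.4 RPKM in the clv3 column and 15.8 RPKM in mp clv3, and WUS, which CLV3 signalling restrains, had 5.69 and 21.8 RPKM. Wild-type plants and clv3 plants behind that column cannot be told apart from the value of 1.4 RPKM, because no wild-type level of CLV3 was used here. Each difference in the report is therefore one from the plants labelled clv3.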
